A study of Mus musculus with 4 samples.

How the data were processed

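Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase cuts and tags open chromatin, in cells sorted from mouse forebrain at postnatal day 4. The labels name 4 samples, 2 per genotype. The control genotype carried Olig2Cre and the Ai14 Cre reporter, and the other genotype carried the MN1:BEND2 fusion in addition. The sort isolated cells of the forebrain by flow cytometry, per the labels' protocols, which do not give the gate.

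The files held 2 MACS2 peak tables, 1 per genotype, with no values per sample. Reads were aligned with Bowtie2 to mm10 and peaks were called with MACS2, per the submitters' processing notes. The versions and the settings are not given in the sources used here. Nor is any adjustment of read positions for the Tn5 cut, any step against duplicate or mitochondrial reads, or any pooling of a genotype's samples before calling. Both lists held mitochondrial peaks, with summit pileups of up to 11586 (ctrl) and 20857 (MN1-BEND2). Mitochondrial reads were therefore present at calling. One file name carries ctrl, as the sample titles do, and the other carries initials that were read as MN1-BEND2. The deposited fragment pileup is a signal height in whole fragments at the peak summit and is not scaled for depth, per the file headers and the values. The deposited fold enrichment is a ratio of this pileup to the caller's local background, each plus 1, and the deposited −log10 q-value compares the pileup with the same background, per the file headers. The deposited p-value column was not used here. The width of each peak is the deposited other measure, in bp. These values belong to each peak within its own list and were used to describe, rank or filter peaks of that list. No accessibility difference was read from them across lists, and the change in height of a shared peak was not tested.

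Peaks on chromosomes 1 to 19, X and Y were used. Of the 42046 ctrl peaks this left out 38 on unplaced contigs and 2 on the mitochondrial genome, and of the 56553 MN1-BEND2 peaks it left out 55 and 3. No peaks overlapped within a list. A peak had a partner, and is called shared, when at least 1 bp overlapped a peak of the other list; the rest are called MN1-BEND2-only and ctrl-only, or 1-list peaks. Overlaps were computed in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and gave the same counts as bedtools 2.31.1. A peak that is missing from a list is not shown to be closed chromatin, since depth and the calling threshold decide what is listed.

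Genes came from a RefSeq gene table of GRCm38.p6, the assembly also known as mm10, with 21887 protein-coding symbols on the chromosomes used. The table gives the start and end of each gene and no strand, exon or sequence. The planned use of transcription starts was therefore replaced by gene boundaries at either end. A gene-end peak has its midpoint within 1000 bp of the boundary of any annotated gene. A peak was assigned to the protein-coding gene with the nearest boundary, within 100000 bp of the midpoint. The planned comparison of 24 sequence motifs needs a genome sequence and was not made, and Bend2 was not analysed here. The planned edgeR test of counts per peak was not made because the files hold no counts per sample.

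With 1 list per genotype there is no replicate error, so no p-value is given and the separate animals or sorts cannot be compared. Shares have exact Clopper-Pearson 95% intervals (scipy 1.17.1), which cover counting error only. The read depth is unknown. The smallest local background that pileup and fold enrichment imply, the background floor, was computed as a stand-in for relative depth. It is proportional to the number of fragments if both lists were made with the same fragment extension and genome size. That number would include the mitochondrial fragments present at calling.

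The 14 gene lists of 20 genes, the rules for named genes and the alternatives were fixed before the data were examined. For each list the share of MN1-BEND2-only peaks among its 1-list peaks was set against 10000 random gene lists of the same size, matched on the number of assigned peaks in 10 bins. A list stood apart outside the central 95% of the random lists, so below the 2.5 percentile or as far from the top, and lists with fewer than 10 such peaks were not counted. Tested on simulated data over 21887 genes, lists given a share of 95% stood apart in 86 of 100 cases, lists given 60% in 78 of 100 and unchanged lists in 2 of 100. The simulated lists held only genes with a 1-list peak, and their peaks were drawn independently. These rates therefore do not carry over to lists in which many members had no such peak. The genes named are Mn1, Olig2, Pdgfra and the Gt(ROSA)26Sor locus; the 12 genes with the largest excess of MN1-BEND2-only over ctrl-only peaks and the 12 with the largest excess of ctrl-only peaks (ties by summed fold enrichment, then by name); up to 2 members of each list in each direction with a difference of at least 2 peaks; and the 5 peaks of each 1-list class with the highest fold enrichment. Alternatives were a reciprocal overlap of 50%, a gap of up to 500 bp, a −log10 q-value of at least 5 in the list searched from or in both lists, the longer list shortened to the size of the other, autosomes alone, a gene-end window of 2500 bp, assignment by gene body with 5000 bp flanks, and removal of gene-end peaks. A filter for strong peaks, added after the data were seen, kept peaks with a fold enrichment of at least 5 and a pileup that, scaled to the other list, reached at least 20. The scale was either the ratio of background floors or the median pileup ratio of shared peaks.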

Results

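The series compared open chromatin in forebrain cells of control mice and of mice in which Olig2Cre switched on MN1:BEND2, a gene fusion found in astroblastoma, a rare brain tumour. Olig2 is a transcription factor of glial and neural progenitors, and Ai14 is a reporter that turns on a red fluorescent protein in cells with Cre. The labels name 2 control and 2 MN1-BEND2 samples, and each genotype is represented by 1 deposited peak list. The ctrl list held 42006 peaks on chromosomes 1 to 19, X and Y, and the MN1-BEND2 list held 56495. The ctrl peaks covered 25.6 Mb with a mean width of 610 bp, and the MN1-BEND2 peaks covered 38.0 Mb with a mean width of 673 bp. Both lists held peaks on chromosome Y (17 in ctrl and 19 in MN1-BEND2). The background floor was 1.16 fragments in the ctrl list and 1.49 in the MN1-BEND2 list, a ratio of 1.28. At 35071 peaks that overlapped 1 to 1, the median ratio of summit pileups was 1.59. The typical shared peak thus had a higher unscaled pileup in the MN1-BEND2 list, and read depth and the ratio of signal to background are not separated here.

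The first comparison asked which regions were listed as open in each genotype. Most control peaks were also in the MN1-BEND2 list, at 36343 of 42006 peaks (86.5%, 95% interval 86.2 to 86.8). Of the MN1-BEND2 peaks, 35832 of 56495 (63.4%, 63.0 to 63.8) had a partner in the control list. There were thus 20663 MN1-BEND2-only peaks and 5663 ctrl-only peaks. The 1-list peaks were the weaker ones of their own list. MN1-BEND2-only peaks had a median summit pileup of 13 against 30 for the shared peaks of that list, and ctrl-only peaks had a median of 10 against 18. The excess of MN1-BEND2-only peaks was spread over the genome: the share of MN1-BEND2 peaks without a partner ranged from 32.7% on chromosome 19 to 39.2% on chromosome 13 across the autosomes and X.

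The 2 numbers depended on how the lists were scaled to each other. Among strong peaks scaled by the background floors, 1536 of 21792 MN1-BEND2 peaks (7.05%, 6.71 to 7.40) and 313 of 20486 ctrl peaks (1.53%, 1.36 to 1.71) had no partner. Scaled by the shared-peak ratio, these were 750 of 17426 (4.30%, 4.01 to 4.62) and 806 of 25191 (3.20%, 2.99 to 3.42).

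**Figure D1:**
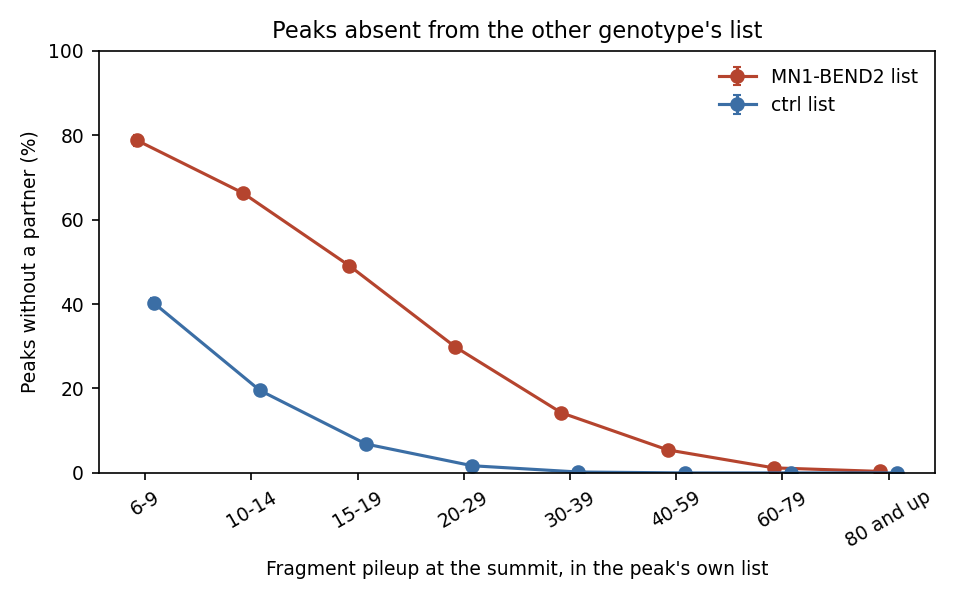
The share of peaks without a partner in the other list (vertical axis, percent) is plotted against the fragment pileup at the peak summit in bins (horizontal axis, fragments), for the MN1-BEND2 and the ctrl list. Bars are exact 95% intervals and are mostly smaller than the points. Pileup is not scaled between the lists, and its median ratio at shared peaks was 1.59 (MN1-BEND2 over ctrl), so bins are read within a list. In the MN1-BEND2 list the share was 78.8% at a pileup of 6 to 9 and 29.8% at 20 to 29.

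The position of the peaks relative to genes differed between shared and 1-list peaks. Of the shared peaks of the MN1-BEND2 list, 13024 of 35832 (36.3%, 35.8 to 36.8) lay within 1000 bp of a gene boundary. The share was 13.5% (13.0 to 14.0) for MN1-BEND2-only peaks and 7.93% (7.24 to 8.66) for ctrl-only peaks. Most 1-list peaks therefore lay away from gene ends: 45.0% of MN1-BEND2-only and 49.9% of ctrl-only peaks were inside protein-coding genes, and 41.6% and 42.2% lay outside them. The boundaries include gene 3' ends as well as promoters, since the gene table gave no strand. Among strong peaks scaled by the shared-peak ratio, the gene-end share was 11.7% (9.52 to 14.3) for MN1-BEND2-only and 8.31% (6.50 to 10.4) for ctrl-only peaks, and the intervals overlapped.

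The loci tied to the mouse model were examined next, over the gene and 5000 bp on each side. At Mn1 (gene 433938, chromosome 5, 111417300 to 111457030, mm10), which encodes the transcriptional coregulator that supplies a part of the fusion, the MN1-BEND2 list had 4 peaks and the control list 1. The shared peak spanned the lower gene boundary (111416731 to 111417391 in the MN1-BEND2 list). The 3 MN1-BEND2-only peaks were at 111414072 to 111414464, outside the gene, and at 111426254 to 111427158 and 111446604 to 111447016, inside it. At Pdgfra (gene 18595, chromosome 5, 75151322 to 75198206), the PDGF receptor gene that marks oligodendrocyte progenitor cells (OPCs), the MN1-BEND2 list had 6 peaks and the control list 3. Here 4 peaks were MN1-BEND2-only, among them the regions 75156829 to 75157232 and 75160590 to 75161206 inside the gene, and 3 were left once a gap of 500 bp was allowed. The control list had 1 ctrl-only peak there, at 75198610 to 75199063. Olig2 (gene 50913, chromosome 16, 91225550 to 91228677) had 3 peaks in each list. Only the MN1-BEND2 peak at 91232352 to 91232771 had no partner, and it gained a partner with the same gap. The Gt(ROSA)26Sor locus (chromosome 6, 113067428 to 113077244) had 1 peak in each list, and it was shared. In equal-sized lists, Mn1 had 1 MN1-BEND2-only peak and Pdgfra had 2, beside the 1 ctrl-only peak. Counted over peaks assigned by nearest gene boundary, the excess was 9 at Mn1, 3 at Olig2 and 2 at Pdgfra. Among strong peaks by shared-peak ratio it was 0 at each of them.

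**Figure D2:**
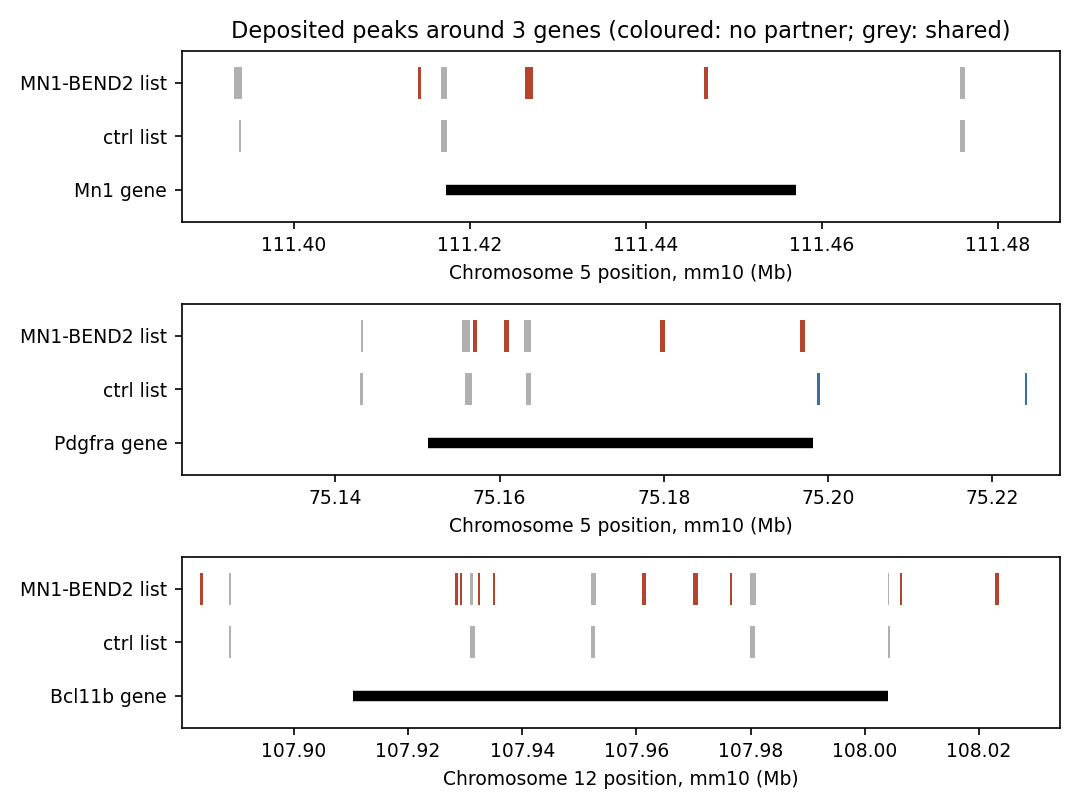
Deposited peaks of both lists are drawn to scale along chromosome 5 around Mn1 and Pdgfra and along chromosome 12 around Bcl11b (horizontal axis, mm10 position in Mb), with 30 kb on each side of the gene; coloured boxes have no partner in the other list and grey boxes are shared. Around Bcl11b the MN1-BEND2 list had 10 peaks without a partner and 5 shared peaks, and the ctrl list had 5 shared peaks.

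Genes were then compared by the 1-list peaks assigned to them. Of 21887 protein-coding genes, 8842 had at least 1 such peak. There were more MN1-BEND2-only than ctrl-only peaks at 7047 genes, more ctrl-only peaks at 1076 and equal numbers at 719. Over all genes 16096 of the assigned 1-list peaks were MN1-BEND2-only and 3921 were ctrl-only, so 80.4% is the level that a gene or a list has to be set against. This level was 54.1% in equal-sized lists and 52.7% among strong peaks by shared-peak ratio.

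The largest excess of MN1-BEND2-only peaks at a gene was 12. Bcl11b, a zinc finger transcription factor of deep-layer cortical and striatal neurons, had 12 MN1-BEND2-only and 0 ctrl-only peaks beside 5 shared ones. Its most enriched MN1-BEND2-only peak lay outside the gene, at 108022746 to 108023524 on chromosome 12, and had a fold enrichment of 14.3. Ror2, a receptor for Wnt ligands, had 12 and 0, and Tjp1, the tight junction scaffold ZO-1, had 12 and 0. Asap1, which encodes a GTPase-activating protein for Arf proteins, also had 12 and 0. Zfp423, a zinc finger transcription factor, and Celf4, a neuronal RNA-binding protein, each had 13 and 1. Next came genes with an excess of 11: Rybp and Bcor, which encode subunits of variant Polycomb repressive complexes, with 11 and 0 and with 12 and 1; Dkk2, a secreted modulator of Wnt signalling, with 11 and 0; Mrtfb, a coactivator of serum response factor, with 11 and 0; and Kctd1 with 12 and 1. Megf10, a phagocytic receptor of astrocytes, had 10 and 0. Bcor is on chromosome X. In equal-sized lists the excess was between 1 (Celf4) and 9 (Rybp) at these 12 genes. By gene body it was between 2 (Rybp) and 13 (Celf4), with 5 at Dkk2 and Mrtfb, and with the stricter list searched from it was between 4 (Mrtfb) and 11 (Ror2). Among strong peaks by shared-peak ratio it was at most 3 (Tjp1), and it was 0 at Rybp, Kctd1, Dkk2, Bcor and Mrtfb.

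The genes with the most ctrl-only peaks had smaller differences, of 3 or 4. Il1rap, the accessory protein of the interleukin-1 receptor, and Ano1, a calcium-activated chloride channel, each had 4 ctrl-only and 0 MN1-BEND2-only peaks. Rora, an orphan nuclear receptor, had 5 and 1, and Grik1, a kainate-type glutamate receptor subunit, had 6 and 3. Myt1, a zinc finger transcription factor expressed in the oligodendrocyte lineage, had 3 ctrl-only peaks and 0 MN1-BEND2-only ones. The most enriched of these had a fold enrichment of 9.43 and lay inside the gene, 31.9 kb from its boundary. Piezo2, a mechanically gated channel, Ino80c, a subunit of the INO80 chromatin remodeller, and Tcp10c each had 3 and 0. Car10, Olfm3 and Fbxl7 each had 5 and 2, and Sema4d, a semaphorin, had 4 and 1. With peaks assigned by gene body, the excess at Rora and at Grik1 turned to 1 MN1-BEND2-only peak, Car10 and Tcp10c had no difference left, and Sema4d, Piezo2 and Ino80c kept 1 ctrl-only peak more. With the stricter list searched from, Grik1, Olfm3, Fbxl7 and Sema4d had no difference left, and MN1-BEND2-only minus ctrl-only was -1 at Rora, Ano1 and Car10. In equal-sized lists this difference was between -6 (Fbxl7) and -3 at the genes named here. Among strong peaks by shared-peak ratio it was -2 at Ino80c, 0 at Rora, Car10 and Sema4d, and -1 at the others.

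Chance was set against these counts by redrawing the list of each 1-list peak at the overall share 1000 times. There were 24 genes with an excess of at least 10 MN1-BEND2-only peaks, and the redraws gave a median of 15 (central 95%, 9 to 22). There were 34 genes with an excess of at least 3 ctrl-only peaks, against a median of 13 (6 to 20). The largest single differences, 12 and 4, were within the redrawn ranges (11 to 16 and 3 to 5.03). The counts of genes thus lay above the redrawn ranges in both directions, while the largest single differences did not. The cut-offs of 10 and 3 were the smallest differences among the 12 genes named in each direction, so they came from these data. No gene was set against redraws of its own number of peaks, and neighbouring peaks are not independent.

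**Figure D3:**
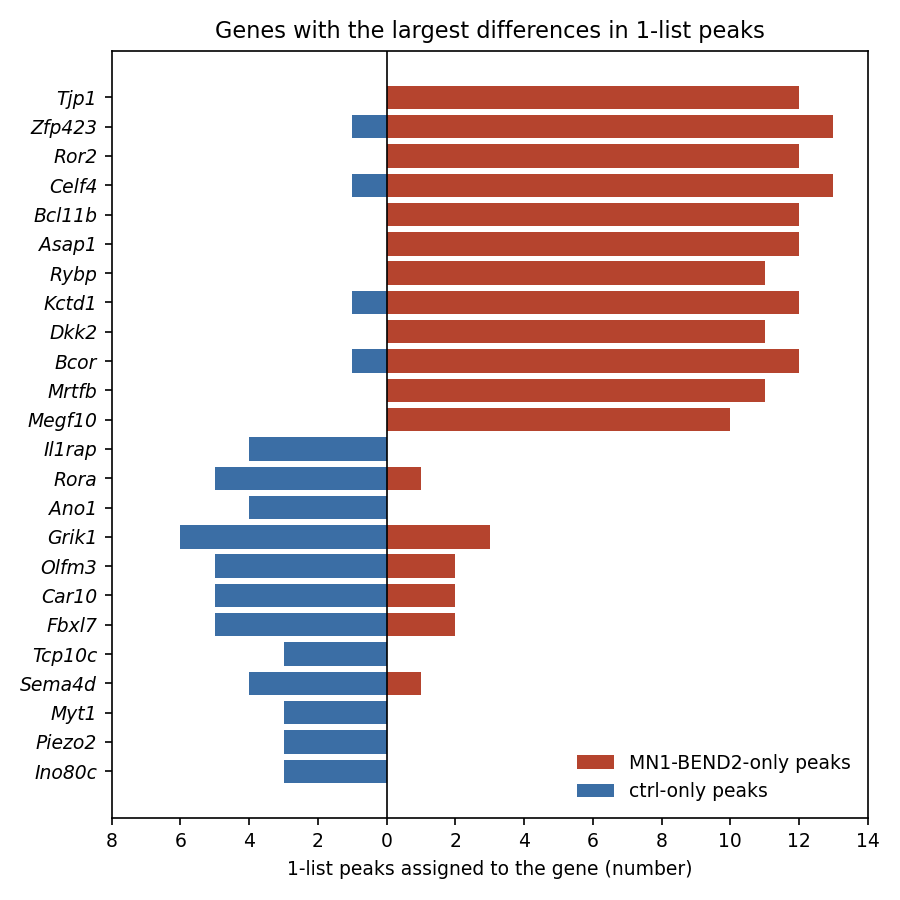
The number of MN1-BEND2-only peaks (to the right) and ctrl-only peaks (to the left) assigned to the 12 genes with the largest difference in each direction is shown on the horizontal axis, with 1 row per gene. The upper 12 genes had 10 to 13 MN1-BEND2-only peaks and the lower 12 had 3 to 6 ctrl-only peaks.

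The gene lists addressed whether cell identity or growth genes took a larger or smaller part in the 1-list peaks than other genes. Of the 14 lists, 1 stood apart from matched random lists, 12 lay within the random range and 1 had too few peaks to be counted. Had all 14 been counted, 0.7 would stand apart by chance. Genes of differentiating and myelinating oligodendrocytes had 23 MN1-BEND2-only and 14 ctrl-only peaks, a share of 62.2% (44.8 to 77.5) against 80.4% for all genes, at the 2.2 percentile. Of its 20 members, 7 had more MN1-BEND2-only peaks, 5 had more ctrl-only peaks, 1 had equal numbers and 7 had no 1-list peak. Ugt8a, an enzyme of myelin galactolipid synthesis, had 2 ctrl-only and 0 MN1-BEND2-only peaks, while Tcf7l2, a transcription factor of differentiating oligodendrocytes, had 11 MN1-BEND2-only and 4 ctrl-only ones and Mbp, the myelin basic protein gene, 2 and 0. The list's percentile was 3.41 by gene body, 8.71 without gene-end peaks, 3.58 in equal-sized lists and 2.78 on autosomes alone, all within the random range. It was 1.99 with a gap of 500 bp and 0.615 with the stricter list searched from, both below it. The list's share minus that of all genes was -18.2 percentage points, and it was -18.0 by gene body, -11.6 without gene-end peaks, -20.8 in equal-sized lists and -16.5 on autosomes alone.

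The other lineage lists lay within the random range. OPC markers had 43 MN1-BEND2-only and 13 ctrl-only peaks (76.8%, percentile 27.0), with 13 members that had more MN1-BEND2-only peaks and 2 that had more ctrl-only peaks. Bcas1 and Xylt1 each had 6 and 0, and Pcdh15 had 0 and 2. In equal-sized lists the excess was 4 at Bcas1 and -1 at Xylt1, and by gene body it was 1 at Pcdh15. Astrocyte markers had 43 and 16 (72.9%, percentile 11.4), with Nfib, a transcription factor of gliogenesis, at 10 and 2 and the glutamate transporter gene Slc1a3 at 8 and 2. In equal-sized lists the excess was -2 at Nfib and 1 at Slc1a3. Neural stem and radial glia markers had 58 and 9 (86.6%, percentile 90.2), and 16 of 20 members had more MN1-BEND2-only peaks. Sox1 and Sox2, transcription factors of neural progenitors, each had 7 and 0, but by gene body the excess was 0 at Sox1 and 1 at Sox2. Ependymal and motile cilium genes had 27 and 7 (79.4%, percentile 45.0), with Tekt1 and Ccdc40 at 3 and 0 each and Rfx3, a ciliogenesis transcription factor, at 2 and 4.

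Neuronal lists went to both sides of the overall share. Dorsal forebrain and excitatory neuron genes had 53 and 7 (88.3%, percentile 93.5), with 17 of 20 members that had more MN1-BEND2-only peaks. Besides Bcl11b, Cux2, an upper-layer cortical transcription factor, had 7 and 0, and Lhx9 had 0 and 2. Ventral forebrain and interneuron genes had 49 and 10 (83.1%, percentile 69.4), with Lhx8, a transcription factor of ventral telencephalic neurons, at 9 and 1 and Meis2 at 9 and 3. Pan-neuronal genes had 50 and 19 (72.5%, percentile 9.86), with Celf4 at 13 and 1 and Myt1l at 6 and 2.

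Growth-related lists were close to the overall share or above it, within the random range. Receptor tyrosine kinase and growth factor genes had 57 and 14 (80.3%, percentile 50.8), with Fgfr2 at 8 and 2 and Pdgfb, a ligand of PDGF receptors, at 6 and 0. Cell cycle genes had 26 and 3 (89.7%, percentile 89.1), with the cyclin-dependent kinase gene Cdk6 at 7 and 0 and the cyclin gene Ccnd2 at 5 and 1. Apart from the growth-related lists, Hox cluster genes had 14 and 1 (93.3%, percentile 79.5), with Hoxc4 at 5 and 0. Of the 20 Hox members, 12 had no 1-list peak. Their random range was 50 to 100%, so no share could lie above it. Of cell types that a sort could carry along, microglia and macrophage markers had 22 and 4 (84.6%, percentile 64.1), with Runx1 at 8 and 1 and Laptm5 at 3 and 0. The random range for these markers also reached 100%. Endothelial and mural markers had 35 and 7 (83.3%, percentile 64.7), with the VEGF receptor gene Flt1 at 8 and 0 and Emcn at 4 and 1. Housekeeping genes had 6 and 2, too few to be counted, with Tubb5 at 2 and 0. With strong peaks no list kept 10 1-list peaks, so none could be set against random lists there.

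**Figure D4:**
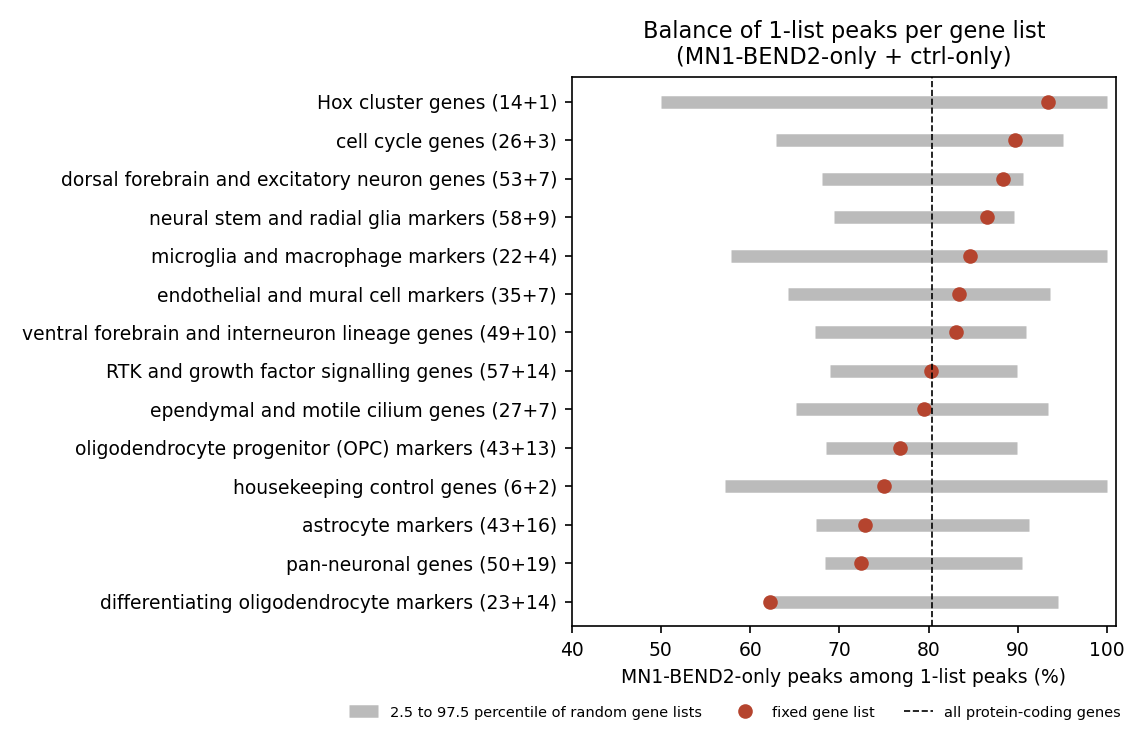
The share of MN1-BEND2-only peaks among 1-list peaks (horizontal axis, percent) is shown for each fixed gene list as a point, with the number of MN1-BEND2-only and ctrl-only peaks in brackets; grey bars span the central 95% of 10000 random lists, and the dashed line marks all genes at 80.4%. The list of differentiating oligodendrocyte markers, at 62.2%, lies just below its bar, and the other points lie inside theirs.

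The most enriched 1-list peaks were also located. The ctrl-only peaks with the highest fold enrichment were on chromosome 4 at 56375794 to 56376198 (13.4-fold, in no annotated gene), on chromosome 2 at 33037412 to 33037927 inside Garnl3 (12.6-fold), on chromosome 3 at 107348796 to 107349459 in no annotated gene (12.1-fold), on chromosome 9 at 70298257 to 70298665 inside Myo1e and the long noncoding RNA gene Gm40531 and on chromosome 17 at 13305980 to 13306246 inside the long noncoding RNA gene Gm36684 (11.6-fold). The MN1-BEND2-only peaks with the highest fold enrichment were narrow. They were on chromosome 12 at 3109867 to 3110120 (36.4-fold, 254 bp wide, in no annotated gene), on chromosome 6 at 103649047 to 103649297 inside Chl1 (35.3-fold, 251 bp), on chromosome 16 at 98107497 to 98107765 in no annotated gene (25.7-fold, 269 bp), on chromosome 1 at 100180107 to 100180420 inside Cntnap5b (24.8-fold, 314 bp) and on chromosome 17 at 70963639 to 70963904 inside the long noncoding RNA gene Gm46595 (23.5-fold, 266 bp). Of these MN1-BEND2-only peaks, those on chromosomes 12 and 6 had summit pileups of 1543 and 1094. Those on chromosomes 16, 1 and 17 had 103, 88 and 167, against a median of 13 for all MN1-BEND2-only peaks. The smallest peak of the MN1-BEND2 list was 251 bp wide and that of the ctrl list 253 bp.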

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

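The tests of depth by the background floors, of the OPC list and of peak width were chosen after the result was seen. So was the use of the stricter list for the low share at oligodendrocyte differentiation genes. The other tests in this part were set down before theirs.

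The mitochondrial genome, which is outside the comparisons above, held 3 peaks in the MN1-BEND2 list and 2 in the ctrl list. The highest summit pileup divided by the list's background floor was 13995 in the MN1-BEND2 list and 9958 in the ctrl list. It was noted because it is a signal in data no comparison used that lay above its level in the control.

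The MN1-BEND2 list had more peaks without a partner than the ctrl list. Lower depth behind the ctrl list was tested as the whole cause. Strong peaks scaled by the background floors were then expected to lack a partner equally often in both lists. The share was 5.52 percentage points higher in the MN1-BEND2 list, with intervals apart. For a higher summit pileup over all shared peaks in the MN1-BEND2 list as the whole cause, the same was expected with the shared-peak scale. There 1.10 percentage points were left, again with intervals apart, although the count of such peaks was lower in the MN1-BEND2 list (750 against 806). Neither scale left equal shares, but each filter for strong peaks changed the peaks and the scale together. The shared-peak filter kept 17426 MN1-BEND2 and 25191 ctrl peaks, with a fold limit that was not scaled, so the peaks compared were not alike. The 1.10 points left there therefore cannot decide whether the higher pileup was the whole cause. The higher pileup may stand for a cleaner library or for a broad opening of chromatin with the fusion, which 1 list per genotype cannot separate.

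The low MN1-BEND2-only share at oligodendrocyte differentiation genes rested on 23 MN1-BEND2-only and 14 ctrl-only peaks. The stricter list searched from drops peaks near the calling limit of their own list, and it left 11 MN1-BEND2-only and 6 ctrl-only peaks. The share was then 64.7% (38.3 to 85.8) against 89.8% for all genes, at the 0.615 percentile. The low share thus remained without such peaks, but it rested on few peaks. This setting was not the test set down for that explanation. Places near the limit of the other list could also account for the low share. Among strong peaks, scaled to that list, 1 MN1-BEND2-only and 4 ctrl-only peaks were left, at the 21.5 percentile, too few to decide. Fewer oligodendrocyte-lineage cells in the MN1-BEND2 sort would lower the OPC list as well, and that list was at the 27.0 percentile, neither under the limit nor above the middle. The OPC list was at the 5.27 percentile with the stricter list searched from and at 41.5 in equal-sized lists, within the random range in both. Both cannot be told apart from an effect of the fusion on differentiation, which stays untested.

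The 5 most enriched MN1-BEND2-only peaks were narrow, from 251 to 314 bp. The 43 with a fold enrichment above the highest ctrl-only value of 13.4 had a median width of 577 bp. Of these, 5 (11.6%, 3.89 to 25.1) were within 10% of the smallest ctrl width, so at most 278.3 bp wide. This compares with 2 of 3471 shared peaks (0.0576%) above the same value. These 5 are not the same set as the 5 most enriched peaks, since the peak inside Cntnap5b was 314 bp wide. Regions just under the width limit of the caller in the ctrl list may account for these few, since such a region would be left out whatever its height. That stays open for them without reads; the others were wider. Regions of unusually high signal were not filtered out of either list, and no biological explanation was tested.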

How the results depend on the processing

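No paired analysis was possible because each genotype has 1 list with no values per sample; for the same reason no replicate could be left out, and the counts per peak and the motif comparison were not run. The strong-peak filters and the comparison of named genes across settings were chosen after the data were seen. With both lists stricter, 47543 MN1-BEND2 and 30554 ctrl peaks remained. The share of MN1-BEND2 peaks with a partner was 55.1% with reciprocal overlap, 64.4% with a gap of 500 bp, 70.7% with the stricter list searched from, 58.2% with both lists stricter, 75.6% in equal-sized lists (10253 MN1-BEND2-only and 9710 ctrl-only peaks), 93.0% among strong peaks by background ratio and 95.7% by shared-peak ratio; for ctrl peaks it was 74.1%, 87.2%, 94.3%, 91.3%, 76.9%, 98.5% and 96.8%. It was lower for MN1-BEND2 than for ctrl in each setting, and nearest in equal-sized lists, where equal sizes force the counts together, and among strong peaks by shared-peak ratio. The gene-end share of shared, MN1-BEND2-only and ctrl-only peaks was 44.6%, 23.0% and 15.4% with a 2500 bp window, 42.2%, 14.9% and 9.10% with both lists stricter, and 39.4%, 14.0% and 9.66% in equal-sized lists; among strong peaks by shared-peak ratio it was 54.6% and 11.7% for the first 2. The number of gene lists below the random range went from 1 to 0 by gene body, without gene-end peaks, in equal-sized lists and on autosomes alone. It was also 0 with both strong-peak filters, where too few peaks were left. It stayed 1 with a gap of 500 bp and the stricter list searched from. The Mn1 excess went from 3 to 1 and the Pdgfra excess from 3 to 1 in equal-sized lists, and the Olig2 excess went from 1 to 0 with a gap of 500 bp. Among named genes the excess reversed to 1 at Rora, Grik1 and Pcdh15 and to -1 at Emcn by gene body, to -1 at Xylt1 and Ccdc40 and -2 at Nfib in equal-sized lists, to 1 at Rfx3 with the stricter list searched from, and to -1 at Myt1l among strong peaks by shared-peak ratio; the cause was not tested. That filter left no difference at 22 of 40 named genes with more MN1-BEND2-only peaks, Mn1, Rybp and Sox1 among them, and at 6 of 16 with more ctrl-only peaks.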

Other observations

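The gene families below were grouped by symbol after the data were seen, except that the prediction for the developmental factors was set down before its test. Fibroblast growth factor genes had 27 MN1-BEND2-only and 0 ctrl-only peaks. Fgf1 had 6 MN1-BEND2-only peaks, and Fgf15 and Fgf18 had 3 each. Dual-specificity phosphatase genes, several of which act on MAP kinases, had 32 and 1, with Dusp4 at 7 and 0 and Dusp26 at 5 and 0. The Fgf family was at the 99.5 percentile of matched random lists, at 98.7 by gene body, 99.9 in equal-sized lists and 91.2 with the stricter list searched from. The Dusp family was at 99.3, 93.0, 97.0 and 89.7 under the same settings. Adamts genes, which encode secreted metalloproteases, had 30 and 15. Most members had more MN1-BEND2-only peaks, such as Adamts3 at 3 and 0, and Adamts6 was at 0 and 3. Their percentile was 1.65, and it was 25.7 by gene body, 1.15 in equal-sized lists and 42.0 with the stricter list searched from. Of 112 families with at least 8 genes and 20 1-list peaks, 3 lay above and 2 below the random range, where 5.6 would lie outside by chance, so none of these stands out beyond the number tested. In this count Zfp genes were also above, with 223 and 35 (percentile 99.1), and Klhl genes also below, with 24 and 12 (2.475). The percentiles given for Fgf, Dusp and Adamts came from another set of random lists, in which Klhl was at 2.55, inside the range.

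One hypothesis is that MN1-BEND2-only peaks gather at genes of developmental transcription factors. It was examined in a set of 94 genes from 14 such families, such as Hox, Lhx, Pax, Fox and Sox. The set need not hold every member of these families. Of its 1-list peaks, 207 were MN1-BEND2-only and 32 ctrl-only, a share of 86.6% at the 98.7 percentile. Not every family went this way. Grouped by symbol, Lhx genes had 22 and 6 (percentile 42.5), Pax genes 29 and 4 (84.0) and Sox genes 46 and 6 (92.15), each within the random range. These counts may cover other members than the pooled set does. The percentile of the pooled genes was 97.1 without gene-end peaks, 88.0 in equal-sized lists, 86.2 with the stricter list searched from and 82.2 by gene body. Among strong peaks it was 71.2 by background ratio (14 and 1 peaks) and 53.3 by shared-peak ratio (6 and 5 peaks). The result may therefore depend on weak peaks outside the genes, and the data leave it open.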
